A study of Homo sapiens with 18 samples.

How the data were processed

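Gene expression was measured by sequencing of polyA RNA from 18 libraries of MV4;11 cells in 6 groups of 3. Per the labels, cells were counted before RNA isolation, ERCC spike-in RNAs were added at lysis, and a stranded mRNA kit was used. The authors' processing fields name HISAT, Cufflinks 2.0.0 and the hg19 build without roles. The gene annotation and the normalization method are not given in the sources used here. The deposited values are FPKM per gene, normalized between libraries by the authors. The table holds 23713 entries, 92 of them spike-ins and 23621 genes. The spike-in values were nearly the same in every library while the gene totals differed, so the values look scaled to the spike-ins. The lowest value was 0.0679 and 0 values were listed as 0, so a small constant appears to have been added. Read depth cannot be recovered from FPKM, and the precision it gives is unknown. The entries MIR1244-3 and MIR1244-2 took 29 to 40.7% of the gene total of a library. Positions are not given, because the reference at hand was of another build.

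Columns were matched to groups by the treatment and time in their names. The columns of the degrader groups carry the compound name dFKBP13, which was taken as dTAG-13, the one degrader in the labels. Columns are numbered 0 to 2 and sample titles 1 to 3, so columns were matched to groups and not to single titles, and libraries are named by group and column number. No pair of columns held identical values.

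Spike-ins were left out of the tests. Genes with at least 1 FPKM in at least 3 of the 18 libraries were tested (12200 genes; 11421 were not). Values were log2 transformed with a pseudocount of 1. One linear model with 6 group means was fitted with limma 3.58.1 in R 4.3.3, with an intensity trend in the prior variance, and moderated two-sided tests were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Each treatment was compared with its vehicle, the 8 h group with the 24 h vehicle. dTAG-13 was compared directly with EPZ-5676 at 96 h and at 24 h with 8 h, the vehicles with each other, and the effects at 96 h and 24 h by an interaction. Library medians were compared by exact permutation tests, two-sided.

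Of 30 gene lists fixed before the data were examined, 27 had at least 5 tested genes. They were tested with limma's camera with a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Fold changes were correlated across genes. For comparisons that share vehicle libraries, unchanged groups with a shared control were simulated in 100 draws. The same simulated values served both such pairs, so they are not specific to either vehicle.

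Named genes followed a rule fixed before the data were examined. It took MLLT1, MYC, MYB, HOXA9, HOXA10, MEIS1, BCL2, CDK6, FLT3 and MEF2C. It added the 6 largest rises and 6 largest falls per vehicle comparison among genes past the threshold with all 3 treated beyond all 3 vehicle libraries, a mean of at least 5 FPKM and no clone, antisense or listed short RNA symbol. From each list described it took up to 4 members with the smallest adjusted p and up to 2 abundant members that did not pass. Direct comparisons, the interaction and the vehicles gave up to 4 genes per direction. Some genes that the rule takes are not reported here.

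The tests were run on simulated data with 200 changed genes among the 12200 genes in the fit. Of genes changed 1.5-fold, 85.1% were recovered at 8 h, 64.2% at 24 h, 86.6% at 96 h of dTAG-13 and 70.1% with EPZ-5676, with 4, 0, 2 and 0 false calls. The simulated treated groups carried no fall of all genes. These rates therefore do not describe the real comparisons at 24 h, at 96 h and with EPZ-5676, where most genes were lower. Alternatives planned before the data were examined were other pseudocounts, filters, scalings, fits, library weights, controls, a replicate block, list tests and leaving out each library. Median scaling, its list test with an estimated correlation, leaving out short RNA entries and leaving out the 8 h libraries were chosen after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.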

Results

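Gene expression was measured in MV4;11 cells, an acute myeloid leukaemia line that carries the MLL-AF4 fusion. Per the labels, the cells express Cas9, lack endogenous ENL and carry ENL fused to a variant of FKBP12. ENL, encoded by MLLT1, is a chromatin reader whose YEATS domain binds acylated histones. dTAG-13 is a bifunctional degrader that brings a protein fused to this FKBP12 variant to the cereblon ubiquitin ligase. EPZ-5676 (pinometostat) inhibits DOT1L, a histone H3 methyltransferase. The 18 libraries of polyA RNA form 6 groups of 3: dTAG-13 at 500 nM for 8, 24 and 96 h, EPZ-5676 at 500 nM for 96 h, and 0.1% DMSO (vehicle) for 24 and 96 h. No vehicle at 8 h is labelled, so the 24 h vehicle served as its control.

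The values are FPKM normalized between libraries by the authors, with spike-in RNAs added per counted cells. Read depth is unknown from these values, so no counting interval is given. Each library held 11323 to 12015 genes at 1 FPKM or more, and 12200 genes entered the tests. Within groups, Pearson's r across genes was 0.962 to 0.975, and 0.995 to 0.998 without short RNA rows; genes are not independent replicates. The labels do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Gene tests are limma's moderated tests on log2(FPKM + 1) with Benjamini-Hochberg adjustment. This scale understates the change of low genes. Group levels are mean FPKM ± SD with n = 3, and fold changes are log2 values ± SE. Each named gene with a largest rise or fall had all 3 treated libraries beyond all 3 control libraries.

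MLLT1 transcripts were present in every library, at levels that do not check the labels, because dTAG-13 acts on the protein. FPKM per gene also cannot separate transcripts of the ENL fusion from those of the endogenous gene. A change of MLLT1 below can therefore not be assigned to either. The libraries with column numbers 0, 1 and 2 held 139.5, 128 and 136 FPKM of MLLT1 in the 24 h vehicle and 121, 115 and 124.5 FPKM in the 96 h vehicle. They held 115, 97.2 and 126 FPKM at 8 h of dTAG-13, 76.8, 81.3 and 91.5 FPKM at 24 h, and 63.7, 55.2 and 66.9 FPKM at 96 h. With EPZ-5676 they held 45.0, 38.6 and 41.5 FPKM. The change was -0.26 ± 0.10 at 8 h (adjusted p = 0.0925). It was called at -0.17 after median scaling (adjusted p = 0.000631) or median centring (0.000474), at -0.26 with a replicate block (0.0228) and at -0.34 without column number 2 of the 8 h group (0.033). MLLT1 fell by 0.69 at 24 h, by 0.95 at 96 h and by 1.51 with EPZ-5676, to adjusted p of 2.09e-05 or lower. After median scaling it fell by 0.18, by 0.45 and by 0.79, and with equal totals the 24 h call was lost (-0.13, adjusted p = 0.128).

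Values across the transcriptome were lower after 24 h and 96 h of treatment. The library median of log2(FPKM + 1) was 4.18 ± 0.06 (SD, n = 3) in the 24 h vehicle and 4.06 ± 0.06 in the 96 h vehicle. It was 4.09 ± 0.15 at 8 h of dTAG-13, 3.69 ± 0.09 at 24 h, 3.59 ± 0.13 at 96 h and 3.38 ± 0.14 with EPZ-5676. The differences from vehicle were -0.09 at 8 h (exact permutation test, two-sided, p = 0.6), -0.48 at 24 h, -0.47 at 96 h and -0.68 with EPZ-5676 (each p = 0.1, the smallest that 3 against 3 libraries allow). The difference at 8 h was -0.006 without column number 1 and -0.15 without column number 2 of the 8 h group. The spike-in rows summed to 9900 to 10358 FPKM in every library, while the other rows summed to 651574 to 1493656. Because this shift moves all genes, counts of list members are given as deposited and after every library was scaled to the same median (median-scaled), a choice made after seeing the data. Counts are over all genes tested; for deposited values the count adjusted over the list alone is added where it differs. List p-values, with the preset or an estimated correlation, are for deposited values unless stated. The one with an estimated correlation and median scaling as well is added where it passed.

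**Figure D1:**
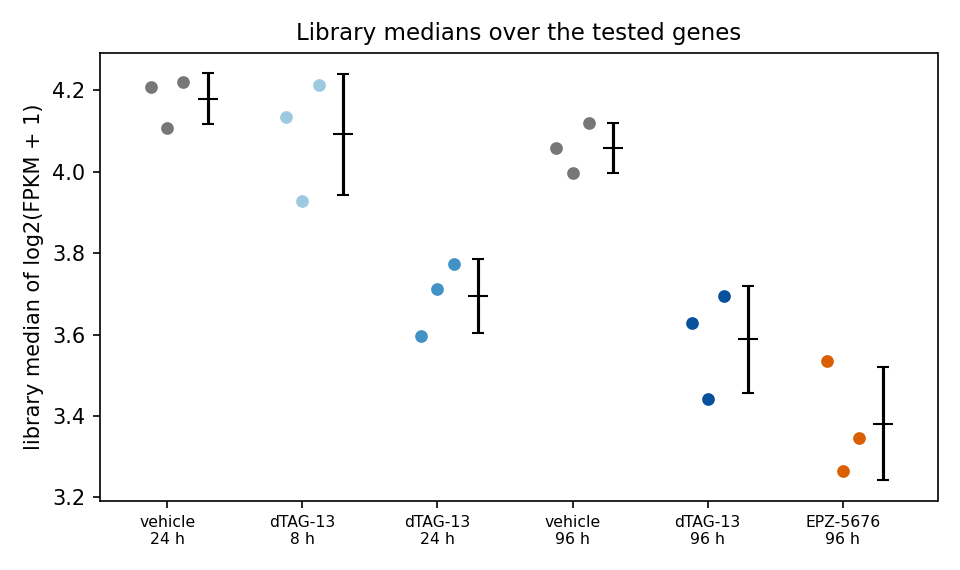
Library median of log2(FPKM + 1) over the 12200 tested genes (y axis) in the 6 groups (x axis). Points are libraries and bars the group mean ± SD (n = 3): the group means are 3.69, 3.59 and 3.38 after dTAG-13 for 24 h, dTAG-13 for 96 h and EPZ-5676, against 4.18 and 4.06 in the vehicles.

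At 8 h of dTAG-13, the comparison that asks which genes changed first, MYC fell from 216 ± 8.04 to 106.5 ± 1.70 FPKM (log2 fold change -1.01 ± 0.09, adjusted p = 7.49e-06). The largest rises were IL7R, a cytokine receptor chain (5.16 to 22.4 FPKM, 1.91 ± 0.12), ANXA1 (1.46 ± 0.15), the chemotactic receptor GPR183 (1.41 ± 0.15), CYP1B1 (1.20 ± 0.13), SEMA6B (1.12 ± 0.20) and the lectin CLEC10A (1.08 ± 0.13). Besides MYC, the largest falls were the retinaldehyde dehydrogenase ALDH1A3 (48.2 to 19.2 FPKM, -1.28 ± 0.10), BAHCC1 (-1.23 ± 0.13), the immediate early factor EGR1 (-1.03 ± 0.20) and PLD6 (-0.96 ± 0.09). The rule also named RNA5SP244, a 5S ribosomal RNA pseudogene, at -6.89 ± 1.48, but its vehicle libraries averaged 177 ± 134 FPKM, and short RNA rows were the least repeatable.

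Of 24 measured genes of the MLL-fusion leukaemia programme, 13 fell and 1 rose at 8 h, and 14 fell and 2 rose when adjusted over the list alone (camera adjusted p = 4.99e-05; adjusted p = 0.782 with an estimated correlation). After median scaling 15 fell and 3 rose. HOXA10 fell by 0.88 ± 0.09, MYB by 0.62 ± 0.09, BCL2 by 0.51 ± 0.09, HOXA9 by 0.48 ± 0.10, MEIS1 by 0.37 ± 0.11 and FLT3 by 0.36 ± 0.10. MEF2C rose by 0.39 ± 0.11, and the change of CDK6 was -0.18 ± 0.12 (adjusted p = 0.363). The calls of MEIS1, FLT3 and MEF2C were lost when some single libraries were left out, with changes of -0.31 to -0.40, -0.32 to -0.35 and 0.34 to 0.38 in those fits. MEIS1 lost its call without any one of the vehicle libraries (adjusted p of 0.0516 to 0.105) or without column number 0 (0.0535) or 1 (0.103) of the 8 h group. FLT3 lost its call without column number 0 (0.108) or 2 (0.0845) of the vehicle or 1 (0.0869) of the 8 h group. MEF2C lost its call without column number 0 (0.0999) or 1 (0.102) of the vehicle, or 0 (0.0928) or 2 (0.069) of the 8 h group, and with only the compared groups in the fit (0.0559).

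Of 30 ribosome biogenesis and MYC target genes, 25 fell at 8 h, and 29 when adjusted over the list alone (median -0.43, camera adjusted p = 1.8e-15; adjusted p = 0.782 with an estimated correlation), and 28 after median scaling. SRM, the spermidine synthase, fell by 0.71 ± 0.10, RRP9 by 0.66 ± 0.10, MYBBP1A by 0.66 ± 0.10 and NOP16 by 0.64 ± 0.10. Of 20 interferon genes, 13 rose, and 14 rose when adjusted over the list alone (median 0.47, camera adjusted p = 3.03e-20; adjusted p = 0.117 with an estimated correlation), and 17 after median scaling. The levels were low: IFIT3 rose from 0.532 to 2.08 FPKM (1.01 ± 0.10), IFI44 from 0.530 to 1.95 FPKM, IFIT2 from 0.478 to 1.38 FPKM and OAS1 from 2.71 to 6.04 FPKM. The more abundant ISG15 did not pass (adjusted p = 0.763).

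Of 24 myeloid maturation and surface genes, 9 rose and 3 fell at 8 h, and 10 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.000953; adjusted p = 0.885 with an estimated correlation), and 11 rose and 4 fell after median scaling. The costimulatory ligand CD86 (0.81 ± 0.11), the oxidase subunit NCF1 (0.81 ± 0.15) and the growth factor receptor CSF1R (0.61 ± 0.11) rose, and the receptor TLR2 fell by 0.49 ± 0.08. NCF1 has near-identical pseudogenes, so its value is uncertain. CIITA, the activator of MHC class II transcription, rose from 2.56 to 5.22 FPKM (0.79 ± 0.15) and was the 1 gene of 11 in the MHC class II list that passed (camera adjusted p = 0.000774; adjusted p = 0.782 with an estimated correlation), and 6 rose after median scaling. Of 10 cyclin-dependent kinase inhibitors, CDKN1A (1.13 ± 0.18) and CDKN1C (0.93 ± 0.16) rose and 1 fell, and 4 rose and 1 fell after median scaling; the list was not called (camera adjusted p = 0.117). Of 17 primary granule genes, 6 fell, among them MS4A3 (-0.66 ± 0.09), PRTN3 (-0.66 ± 0.10) and CTSG (-0.55 ± 0.09), and 7 fell and 1 rose when adjusted over the list alone. After median scaling 7 fell and 3 rose, and the list was not called (camera adjusted p = 0.133). Of 28 mitosis genes 0 passed as deposited and 15 rose after median scaling. Camera called this list up (adjusted p = 0.00105, and 0.885 with an estimated correlation). In all, 391 genes were higher and 1239 lower at 8 h, and 2061 and 2216 after median scaling. The balance turned against the 96 h vehicle (707 higher and 502 lower) and with equal totals (4051 and 670). Without column number 0 of the vehicle 540 were lower, and without column number 2 of the 8 h group 1881. Without column numbers 0 and 1 of the 8 h group in turn, 224 and 622 were higher.

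At 24 h of dTAG-13 against the 24 h vehicle, the macrophage pore protein gene MPEG1 rose from 3.31 ± 0.38 to 10.1 ± 0.466 FPKM (1.37 ± 0.10, adjusted p = 3.01e-07), CD86 from 4.56 to 13.2 FPKM (1.35 ± 0.11), HLA-DRA from 49.1 to 127 FPKM (1.35 ± 0.11), HLA-DPA1 from 3.75 to 10.8 FPKM (1.32 ± 0.13), ALOX5AP from 20.7 to 52.0 FPKM (1.29 ± 0.11) and CIITA from 2.56 to 7.57 FPKM (1.26 ± 0.15). ALDH1A3 fell from 48.2 ± 1.44 to 9.17 ± 0.811 FPKM (-2.28 ± 0.10, adjusted p = 4.6e-10). OAF (-1.69 ± 0.11), BAHCC1 (-1.58 ± 0.13), the alanine transaminase GPT2 (-1.54 ± 0.09), ALOX12 (-1.48 ± 0.09) and the granule protease CTSG (-1.45 ± 0.09) also fell.

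All 11 measured MHC class II genes rose at 24 h in both scalings (median 0.91, camera adjusted p = 1.46e-43), and of the deposited values this list alone kept its call with an estimated correlation (adjusted p = 0.00259, and 0.0127 with median scaling as well). Among them HLA-DMA rose by 1.13 ± 0.10 and HLA-DQB1 by 0.96 ± 0.11; HLA-DQB1 and the DRB genes have similar copies whose reads may be split, so single values are uncertain. Of 24 myeloid genes, 10 rose and 6 fell (camera adjusted p = 1.24e-24; adjusted p = 0.12 with an estimated correlation, and 0.00507 with median scaling as well), and 18 rose and 1 fell after median scaling. S100A8 rose by 1.06 ± 0.10, CSF1R by 0.85 ± 0.11 and the lysozyme gene LYZ by 0.65 ± 0.08.

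Of 24 MLL-fusion programme genes, 22 fell at 24 h (median -0.76, camera adjusted p = 0.00486; adjusted p = 0.848 with an estimated correlation, and 0.039 with median scaling as well). After median scaling 14 fell and 2 rose. HOXA10 fell from 78.5 to 28.9 FPKM (-1.41 ± 0.09), HOXA11 by 1.18 ± 0.10, CPEB2 by 1.04 ± 0.10 and PBX3 by 0.93 ± 0.09. MYC (-0.91 ± 0.09), MYB (-0.97 ± 0.09), MEIS1 (-0.92 ± 0.11), HOXA9 (-0.89 ± 0.10), FLT3 (-0.77 ± 0.10), CDK6 (-0.76 ± 0.12) and BCL2 (-0.57 ± 0.09) fell. The BCL2 change after median scaling was -0.07 (adjusted p = 0.311), and with equal totals CDK6 lost its call (adjusted p = 0.121). MEF2C changed by 0.11 ± 0.11 (adjusted p = 0.35) and rose by 0.55 after median scaling.

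Of 18 integrated stress response genes, which include amino acid synthesis and transport genes, 17 fell at 24 h (median -0.90, camera adjusted p = 0.000906; adjusted p = 0.848 with an estimated correlation, and 0.039 with median scaling as well) and 12 fell and 1 rose after median scaling. The transporter SLC7A5 (-1.17 ± 0.09), the serine synthesis genes PSAT1 (-1.40 ± 0.11) and PHGDH (-1.19 ± 0.11) and ASNS (-0.94 ± 0.09) had the smallest adjusted p. All 30 ribosome biogenesis and MYC target genes fell (camera adjusted p = 1.02e-07; adjusted p = 0.848 with an estimated correlation), 28 of them after median scaling, among them LDHA (-0.92 ± 0.09), ODC1 (-0.91 ± 0.10) and NOP2 (-0.81 ± 0.09). All 30 DNA replication genes fell (camera adjusted p = 5.46e-06; adjusted p = 0.848 with an estimated correlation), 23 of them after median scaling, among them MCM10 (-0.90 ± 0.08), CDC25A (-0.92 ± 0.09) and RRM2 (-0.89 ± 0.09). Of 20 interferon genes, 2 rose and 6 fell, 1 and 5 when adjusted over the list alone, and 8 rose after median scaling (median -0.04; camera called the list up against the lower background, adjusted p = 5.27e-08; adjusted p = 0.49 with an estimated correlation). In all, 247 genes were higher and 9533 lower at 24 h, and 2479 and 2269 after median scaling. Lower calls were 97.5% of the calls as deposited and 47.8% after scaling.

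**Figure D2:**
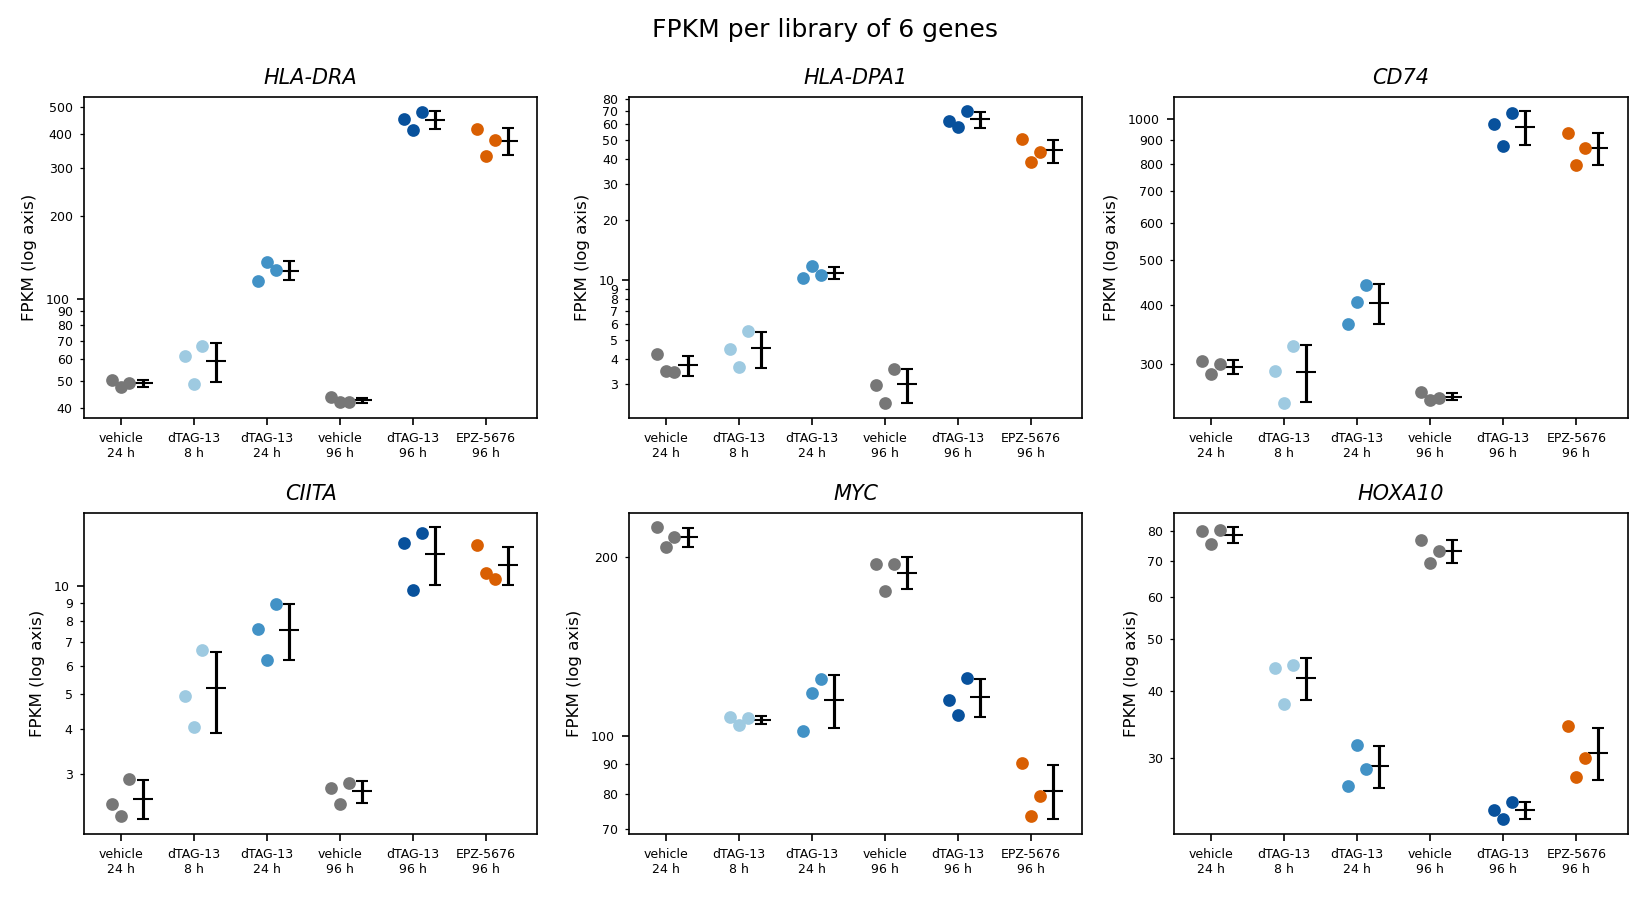
FPKM per library (y axis, log scale) of 6 genes in the 6 groups (x axis). Points are libraries and bars the group mean ± SD (n = 3): mean HLA-DRA was 42.5 FPKM in the 96 h vehicle and 449.5 FPKM at 96 h of dTAG-13, and mean HOXA10 73.2 and 23.9 FPKM.

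At 96 h of dTAG-13 the largest rises were MHC class II genes and MPEG1. HLA-DPA1 rose from 3.003 ± 0.579 to 63.4 ± 5.90 FPKM (4.01 ± 0.13, adjusted p = 1.17e-12), HLA-DRA from 42.5 ± 0.932 to 449.5 ± 34.3 FPKM (3.37 ± 0.11), MPEG1 from 3.30 to 37.9 FPKM (3.17 ± 0.10), HLA-DRB1 from 12.7 to 102 FPKM (2.90 ± 0.12), HLA-DQB1 from 2.29 to 19.1 FPKM (2.62 ± 0.11) and HLA-DRB5 from 1.99 to 15.9 FPKM (2.50 ± 0.16). ALDH1A3 fell from 45.6 ± 4.22 to 2.75 ± 0.258 FPKM (-3.63 ± 0.10, adjusted p = 2.06e-13). DHRS3, a retinal reductase gene, fell by 3.02 ± 0.16, the surface enzyme CD38 by 2.31 ± 0.10, RHBDL3 by 2.10 ± 0.12, OAF by 1.99 ± 0.11 and the chemokine CCL5 by 1.82 ± 0.15. All 11 MHC class II genes rose in both scalings (median 2.50, camera adjusted p = 1.6e-55), and the call held with an estimated correlation (adjusted p = 0.000827, and 0.00792 with median scaling as well).

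Of 24 myeloid maturation genes, 12 rose and 6 fell at 96 h (camera adjusted p = 1.85e-22; adjusted p = 0.157 with an estimated correlation, and 0.00792 with median scaling as well), and 17 rose and 4 fell after median scaling. LYZ rose from 97.0 ± 5.28 to 490 ± 15.1 FPKM (2.33 ± 0.08), S100A8 by 1.98 ± 0.10, CD86 by 1.95 ± 0.11 and the scavenger receptor CD36 by 1.27 ± 0.10. Of the MLL-fusion programme, 22 of 24 genes fell and 1 rose (camera adjusted p = 0.0147; adjusted p = 0.861 with an estimated correlation), and 17 fell and 2 rose after median scaling. HOXA11 fell by 1.66 ± 0.10, HOXA10 by 1.58 ± 0.09, MEIS1 by 1.13 ± 0.11, HOXA9 by 1.07 ± 0.10, MYB by 0.90 ± 0.09, MYC by 0.69 ± 0.09, CDK6 by 0.69 ± 0.12 and FLT3 by 0.67 ± 0.10; with equal totals CDK6 lost its call (adjusted p = 0.193). MEF2C rose by 0.45 ± 0.11. BCL2 was lower by the deposited values (-0.27 ± 0.09, adjusted p = 0.0132) and higher after median scaling (0.22, adjusted p = 0.00417), and lost its call without column number 1 of the dTAG-13 group (-0.16, adjusted p = 0.0948).

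All 28 mitosis genes fell at 96 h in both scalings (median -0.81, camera adjusted p = 8.7e-06; adjusted p = 0.834 with an estimated correlation, and 0.0454 with median scaling as well), among them the kinase gene PLK1 (-1.0 ± 0.10), CENPA (-0.93 ± 0.09) and CCNB1 (-0.94 ± 0.10). All 30 DNA replication genes fell (camera adjusted p = 8.7e-06; adjusted p = 0.834 with an estimated correlation), and 26 after median scaling, including RRM2 (-1.12 ± 0.09), MCM10 (-1.03 ± 0.08) and CDC25A (-1.08 ± 0.09). Of 22 immediate early genes, 16 fell and 1 rose, and 10 fell and 5 rose after median scaling, with ETV4 (-1.72 ± 0.10), KLF2 (-1.47 ± 0.13), IER3 (-1.12 ± 0.12) and IER2 (-0.92 ± 0.11) at the smallest adjusted p; the list was not called against the other genes (camera adjusted p = 0.967). This list and KLF2 were themselves higher in the 96 h than in the 24 h vehicle. Of 30 cytoplasmic ribosomal protein genes, 24 fell as deposited (camera adjusted p = 0.35). After median scaling 23 rose (camera adjusted p = 8.7e-06, and 0.495 with an estimated correlation as well). RPL5 changed from -0.44 to 0.07 between those scalings and RPL8 from -0.46 to 0.05. Neither passed after median scaling (limma adjusted p = 0.367 and 0.542). In all, 398 genes were higher and 9290 lower, and 2861 and 3390 after median scaling. Lower calls were 95.9% of the calls as deposited and 54.2% after scaling.

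The degrader's effect at 96 h was set against its effect at 24 h, each against its own vehicle, as an interaction. The MHC class II genes rose more at 96 h: 10 of 11 passed, and all 11 when adjusted over the list alone or after median scaling (median difference 1.66, camera adjusted p = 2.83e-62; adjusted p = 0.000471 with an estimated correlation, and 0.000304 with median scaling as well). HLA-DPA1 differed by 2.69 ± 0.19, HLA-DRA by 2.02 ± 0.15, HLA-DRB1 by 2.0 ± 0.17 and HLA-DRB5 by 1.87 ± 0.22. The largest negative differences were DHRS3 (-2.70 ± 0.23), ALDH1A3 (-1.36 ± 0.14), SIRPG (-1.18 ± 0.14) and CD38 (-1.17 ± 0.14). DHRS3 also differed between the vehicles. In all, 52 genes had a more positive and 38 a more negative effect at 96 h, and 356 and 320 after median scaling. Without column number 1 of the 24 h dTAG-13 group 57 genes passed. The fold changes at both times, which share no library, correlated across genes with Pearson's r = 0.505 and Spearman's rho = 0.81, and r = 0.843 without short RNA rows. On this scale the fall grew with the level of the genes. The median was -0.14 under 1 FPKM and -0.57 at 50 to 100 FPKM at 24 h, and -0.21 and -0.59 at 96 h. A fall shared by all genes can thus give a correlation, and no reference for it was made. After median scaling r was 0.465.

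At 24 h compared directly with 8 h of dTAG-13, HLA-DPA1 (1.10 ± 0.13), S100A8 (1.16 ± 0.10) and the immediate early gene FOS (1.19 ± 0.28) were higher. RNA5SP244 was also called, at 4.08 ± 1.48, but not after median scaling (adjusted p = 0.066) nor without column number 1 of the 24 h group (adjusted p = 0.0962), and its 24 h level was 34.5 ± 45.2 FPKM. RHBDL3 (-1.38 ± 0.12), PHGDH (-1.34 ± 0.11), the sterol pathway gene ACAT2 (-1.16 ± 0.09) and A4GALT (-1.13 ± 0.17) were lower. All 11 MHC class II genes were higher in both scalings (camera adjusted p = 9e-62; adjusted p = 0.000491 with an estimated correlation, and 0.00269 with median scaling as well). Of 20 interferon genes, 16 were lower at 24 h than at 8 h, and 9 lower and 1 higher after median scaling (camera adjusted p = 0.0155; adjusted p = 0.815 with an estimated correlation). In all, 97 genes were higher and 9303 lower at 24 h than at 8 h, and 1569 and 1077 after median scaling. Fold changes at 8 h and 24 h correlated with r = 0.592 and rho = 0.706. Unchanged groups simulated with a shared control gave r = 0.516 on average and up to 0.671, so this r lies in their range. Their rho was 0.473 on average. These simulated values were not specific to the 24 h vehicle. Without short RNA rows r was 0.73 against 0.5 simulated on average. The covariance was 0.0847 against 0.0438 simulated, and 0.0442 against 0.0071 without short RNA rows, and part of the excess may come from the shared controls.

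DOT1L inhibition with EPZ-5676 for 96 h was asked of the same 96 h vehicle. MHC class II genes again rose most: HLA-DPA1 from 3.003 ± 0.579 to 44.3 ± 5.92 FPKM (3.50 ± 0.13, adjusted p = 1.79e-11), HLA-DRA from 42.5 to 376 FPKM (3.11 ± 0.11), HLA-DRB1 by 2.61 ± 0.12, HLA-DQB1 by 2.37 ± 0.11, HLA-DRB5 by 2.19 ± 0.16 and HLA-DMA by 1.83 ± 0.10. All 11 measured members rose in both scalings (median 2.19, camera adjusted p = 2.39e-39; adjusted p = 0.0041 with an estimated correlation, and 0.0375 with median scaling as well). EGR1 fell from 17.2 ± 2.43 to 1.80 ± 0.283 FPKM (-2.70 ± 0.20, adjusted p = 2.58e-09) and PPP1R27 from 544 ± 34.2 to 83.1 ± 7.46 FPKM (-2.70 ± 0.12). In the 24 h vehicle EGR1 averaged 9.54 ± 1.39 FPKM, so the size of its fall depends on the vehicle. The fatty acid desaturases FADS2 (-2.42 ± 0.10) and SCD (-2.39 ± 0.09), the cytokine TNF (-2.41 ± 0.15) and CHSY1 (-2.19 ± 0.10) were the other largest falls.

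All 20 cholesterol synthesis genes fell with EPZ-5676 in both scalings (median -1.70, and -0.997 after median scaling; camera adjusted p = 1.24e-06; adjusted p = 0.803 with an estimated correlation). DHCR7 fell by 1.97 ± 0.09, SQLE by 1.91 ± 0.09 and IDI1 by 1.86 ± 0.09. These 20 genes also fell at 96 h of dTAG-13 (median -0.72, camera adjusted p = 0.0034, and 0.861 with an estimated correlation). After median scaling 14 fell and 1 rose with dTAG-13. The following counts are again for EPZ-5676. All 28 mitosis genes fell in both scalings (camera adjusted p = 1.9e-07; adjusted p = 0.803 with an estimated correlation, and 0.0375 with median scaling as well), with CCNA2 (-1.72 ± 0.09), PLK1 (-1.76 ± 0.10) and CDK1 (-1.65 ± 0.09) among them. All 30 DNA replication genes fell (camera adjusted p = 1.3e-08; adjusted p = 0.803 with an estimated correlation), and 29 fell and 1 rose after median scaling; CDC25A (-1.98 ± 0.09), RRM2 (-1.90 ± 0.09), MCM10 (-1.80 ± 0.08) and GINS1 (-1.71 ± 0.08) had the smallest adjusted p. All 13 heat shock genes fell in both scalings (camera adjusted p = 0.000367; adjusted p = 0.803 with an estimated correlation), including HSPH1 (-1.72 ± 0.09) and HSPD1 (-1.57 ± 0.09). Of 15 unfolded protein response genes all fell, and 11 fell and 1 rose after median scaling (camera adjusted p = 0.0146; adjusted p = 0.837 with an estimated correlation), including XBP1 (-1.77 ± 0.10) and MANF (-1.40 ± 0.08). At 96 h of dTAG-13 all 13 heat shock genes fell, and 11 after median scaling (camera adjusted p = 0.00146, and 0.834 with an estimated correlation). There 14 unfolded protein response genes fell, and 2 fell and 2 rose after median scaling (camera adjusted p = 0.191).

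Of 20 interferon genes, 9 rose and 4 fell with EPZ-5676, and 18 rose after median scaling (camera adjusted p = 2.17e-13; adjusted p = 0.211 with an estimated correlation). IFI6 rose by 1.33 ± 0.20, MX2 by 0.75 ± 0.11 and OAS1 by 0.71 ± 0.12. Of 30 cytoplasmic ribosomal protein genes, 19 fell as deposited, 18 when adjusted over the list alone, but all 30 rose after median scaling. As deposited, camera called the list up against the lower background (adjusted p = 0.0193, and 0.862 with an estimated correlation). After median scaling the camera adjusted p was 4.71e-09, and 0.313 with an estimated correlation as well. RPL8 changed from -0.52 to 0.22 between those scalings and RPS15 from -0.48 to 0.25. Of 24 myeloid genes, 9 rose and 7 fell, and 18 rose and 4 fell after median scaling (camera adjusted p = 9.44e-10; adjusted p = 0.715 with an estimated correlation). The list's median was 0.06 and its mean -0.05. S100A8 (1.25 ± 0.10) and CD86 (1.04 ± 0.11) rose, and the nuclear antigen gene MNDA (-2.09 ± 0.11) and the Fc receptor FCGR1A (-1.64 ± 0.11) fell.

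Among the leukaemia genes, PBX3 (-1.54 ± 0.09), CDK6 (-1.39 ± 0.12), FLT3 (-1.29 ± 0.10), HOXA10 (-1.24 ± 0.09), LMO2 (-1.23 ± 0.08), MYC (-1.21 ± 0.09), MYB (-1.08 ± 0.09), HOXA9 (-1.05 ± 0.10), BCL2 (-1.03 ± 0.09) and MEIS1 (-0.85 ± 0.11) fell with EPZ-5676. With equal totals MEIS1 lost its call (-0.04, adjusted p = 0.445). MEF2C changed by 0.16 ± 0.11 (adjusted p = 0.204) and rose by 0.79 after median scaling. Of the 24 list genes 19 fell, and 14 fell and 5 rose after median scaling; the list was not called against the other genes (camera adjusted p = 0.22). In all, 540 genes were higher and 9650 lower, and 4150 and 4348 after median scaling. Lower calls were 94.7% of the calls as deposited and 51.2% after scaling.

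**Figure D3:**
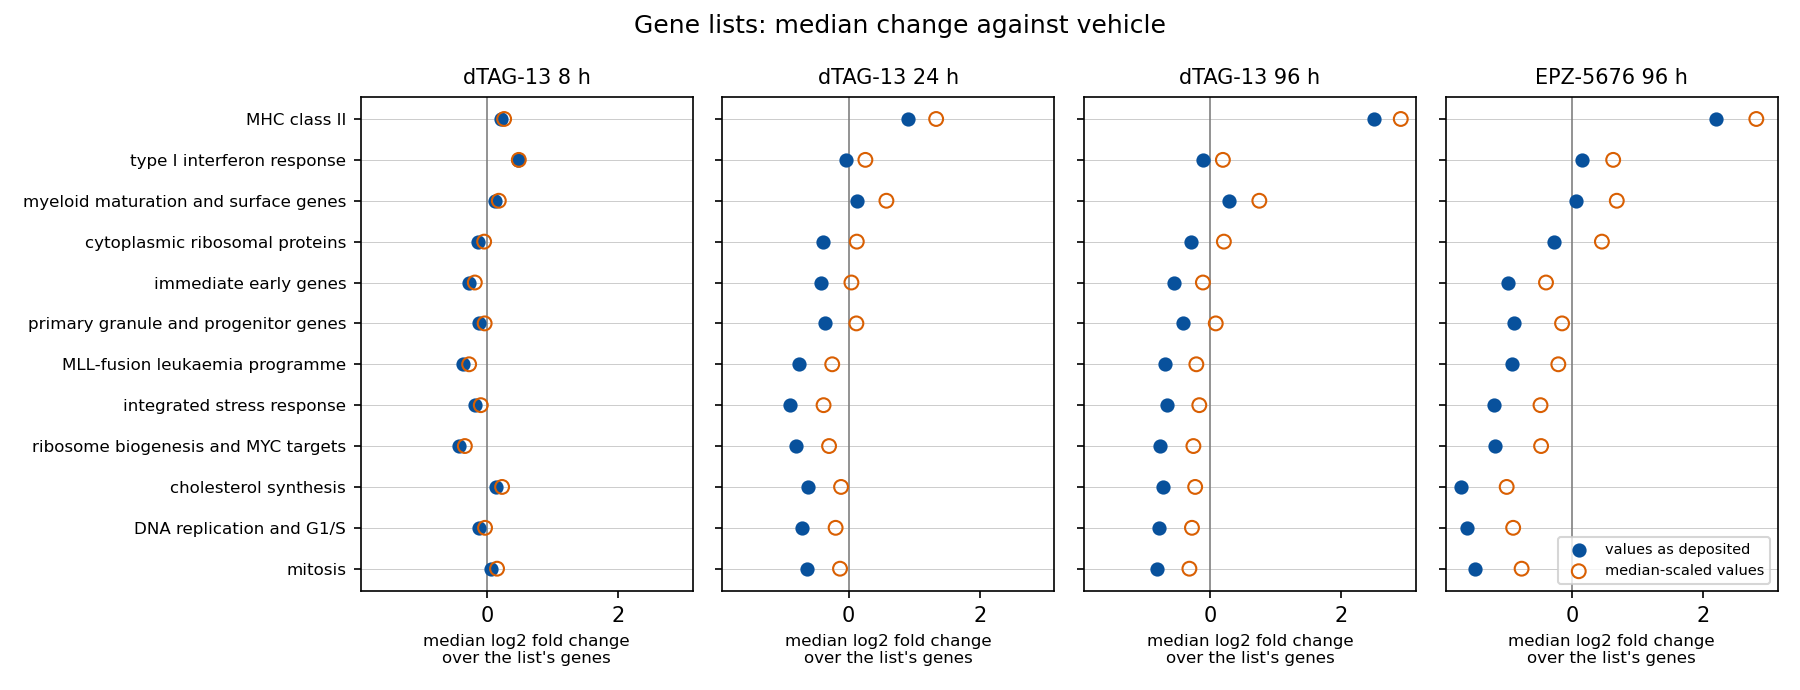
Median log2 fold change against vehicle over the genes of 12 lists (x axis) in the 4 comparisons, from deposited values (filled) and from median-scaled values (open). The MHC class II median is 2.50 and 2.19 at 96 h of dTAG-13 and EPZ-5676 as deposited, while the median of the ribosomal protein genes changes sign with the scaling at 24 h and 96 h.

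dTAG-13 and EPZ-5676 were compared directly at 96 h and at the same concentration. IL7R (13.4 ± 0.605 against 1.70 ± 0.0706 FPKM, 2.41 ± 0.12), FOS (2.04 ± 0.28), EGR1 (2.01 ± 0.20) and GPR183 (1.85 ± 0.15) were higher with dTAG-13. FOS varied widely between the dTAG-13 libraries (75.8 ± 48.7 against 15.7 ± 2.14 FPKM), so the size of its difference is uncertain. The histone gene HIST1H2AC (-1.72 ± 0.19), SPOCK1 (-1.70 ± 0.10) and ALDH1A3 (-1.69 ± 0.10) were lower with dTAG-13. RNA5SP244 was called lower at -4.32 ± 1.48 but lost its call without column number 0 (adjusted p = 0.108) or 1 (0.0862) of the dTAG-13 group, or 0 (0.0627) or 2 (0.0649) of the EPZ-5676 group, with changes of -3.56 to -4.24. All 20 cholesterol synthesis genes (camera adjusted p = 1.05e-13; adjusted p = 0.582 with an estimated correlation), all 28 mitosis genes (camera adjusted p = 2.56e-11; adjusted p = 0.873 with an estimated correlation, and 0.0428 with median scaling as well) and 29 of 30 DNA replication genes (camera adjusted p = 2.95e-15; adjusted p = 0.745 with an estimated correlation, and 0.0428 with median scaling as well) were higher with dTAG-13. After median scaling these counts were 20, 28 and 29, with 1 DNA replication gene lower. Against vehicle, as deposited, all genes of these lists fell at 96 h of dTAG-13 too, so they were lowered less than with EPZ-5676. Of 20 interferon genes, 11 were lower with dTAG-13, and 15 after median scaling (camera adjusted p = 2.3e-10; adjusted p = 0.582 with an estimated correlation).

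In all, 4722 genes were higher and 599 lower with dTAG-13 than with EPZ-5676, and 3352 and 3141 after median scaling. The fold changes of both treatments against the shared vehicle correlated across genes with Pearson's r = 0.722 and Spearman's rho = 0.81. The same simulated values served here and were not specific to the 96 h vehicle. They were r = 0.516 on average and up to 0.671, and rho = 0.473 on average. Without short RNA rows r was 0.802 against 0.5 simulated on average. A fall that grew with the level of the genes, as with both treatments here, can also raise r, which was 0.677 after median scaling. The covariance was 0.173 against 0.0438 simulated. After median scaling 2382 genes were higher with both, where independent lists would share 973, and 2748 were lower with both, where independent lists would share 1208. A further 261 genes were called in opposite directions. The 3 vehicle libraries are too few to split, so part of the excess may come from the shared controls. The fold changes of dTAG-13 at 24 h and EPZ-5676 at 96 h share no library. They correlated with r = 0.474 and rho = 0.771, and with r = 0.784 without short RNA rows. After median scaling 2023 genes were higher with both, where independent lists would share 843, and 1922 were lower with both, against 809. A further 198 were called in opposite directions. This pair sets 24 h against 96 h, so the part due to shared controls at 96 h stays unknown.

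The vehicles at 96 h and 24 h gave the background. Of 12200 genes, 4 were higher and 1 lower at 96 h: DHRS3 (4.51 to 11.99 FPKM, 1.23 ± 0.16), TRIB1 (0.87 ± 0.11), DHRS2 (1.34 ± 0.16) and KLF2 (0.78 ± 0.13) rose, and IL7R fell by 0.74 ± 0.12. DHRS2 and KLF2 were named after their values were seen. IL7R lost its call without column number 0 (adjusted p = 0.172) or 1 (0.146) of the 96 h vehicle, or 0 (0.228) or 2 (0.139) of the 24 h vehicle, with changes of -0.69 to -0.73 in those fits. Without column number 1 of the 96 h vehicle 3 genes passed. Of 22 immediate early genes, 1 was higher over all genes tested and 8 when adjusted over the list alone (median 0.23, camera adjusted p = 1.43e-39; adjusted p = 0.0199 with an estimated correlation, and 0.013 with median scaling as well), and 6 after median scaling. By camera 10 of 27 lists were called between the vehicles, and this one alone with an estimated correlation. Camera also called up, against the lower background, cholesterol synthesis (adjusted p = 1.19e-07), NF-kB (1.67e-05), myeloid maturation (0.00012), primary granule (0.00471) and lymphoid genes (0.0227). Their median changes were 0.028, -0.002, -0.009, -0.043 and -0.027 in that order, against -0.118 over all genes. Called down were DNA replication (0.00012), ribosome biogenesis (0.00471), heat shock (0.00849) and mitosis genes (0.0287). No member of these 9 lists passed as deposited over all genes tested, so camera calls of this size also arise between vehicles. Over all genes, after median scaling 79 genes were higher and 16 lower.

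Of 5 erythroid and megakaryocyte markers, 3 fell at 24 h and at 96 h of dTAG-13, and 1 rose and 1 fell at each time after median scaling (camera adjusted p = 0.945 and 0.97). With EPZ-5676, 1 rose and 3 fell, and 3 rose and 2 fell after median scaling (camera adjusted p = 0.527). Of 6 lymphoid markers, 3 fell at 24 h and 2 at 96 h, and 2 rose and 1 fell, then 3 rose and 2 fell, after median scaling (camera adjusted p = 0.345 and 0.191). With EPZ-5676, 1 rose and 2 fell, and 3 rose after median scaling (camera adjusted p = 0.0712). Of 7 measured dendritic cell markers, 2 rose and 1 fell at 8 h, 3 and 2 when adjusted over the list alone (camera adjusted p = 0.00523; adjusted p = 0.782 with an estimated correlation), and 4 rose and 1 fell after median scaling. At 24 h, 2 rose and 3 fell (camera called the list up, adjusted p = 0.00462; adjusted p = 0.848 with an estimated correlation), and 4 rose and 1 fell after median scaling. At 96 h of dTAG-13, 2 rose and 4 fell (camera called the list up, adjusted p = 0.00646; adjusted p = 0.834 with an estimated correlation), and 3 rose and 2 fell after median scaling. With EPZ-5676, 2 rose and 5 fell, and 4 rose and 2 fell after median scaling (camera adjusted p = 0.106). The B-cell markers CD79A and MS4A1 averaged 1.09 and 0.102 FPKM in the 96 h vehicle, 1.09 and 0.0997 FPKM at 96 h of dTAG-13, and 1.57 and 0.0953 FPKM with EPZ-5676.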

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

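The effect of dTAG-13 differed between 96 h and 24 h by the interaction test for 90 genes and 9 lists; with an estimated correlation 1 list stayed called, and 2 with median scaling as well. The median interaction of the MHC class II list was 1.66 in log2. HLA-DPA1 differed by 2.69, HLA-DRA by 2.02, HLA-DRB1 by 2.0 and HLA-DRB5 by 1.87. DHRS3 differed by -2.70, ALDH1A3 by -1.36, SIRPG by -1.18 and CD38 by -1.17. Of 100 drawn splits of the 12 libraries, 2 gave as many genes, the real one included. The highest other split gave 618 genes, several times the real count. As many lists were called in 42 of the 100 splits, with 15 lists in the highest other split. The splits exchanged 24 h and 96 h libraries within dTAG-13 and within vehicle, and kept treated and vehicle libraries apart. The structure of the samples by time thus enters them by construction. They are no reference without a difference between the times, and chance is not excluded for either count.

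The tests of the MHC class II rise were chosen after the result was seen. RNA from B cells would bring their abundant transcripts, but the highest mean of 8 B-cell markers in the treated groups at 96 h was 1.57 FPKM (CD79A with EPZ-5676), against 1.09 FPKM in the vehicle. Reads shared between similar HLA genes would not raise members without a near-identical copy, and 5 of 5 such members measured were higher at 24 h and 96 h of dTAG-13 and with EPZ-5676. A response of the cells to loss of ENL or to DOT1L inhibition may account for the rise and stays a hypothesis, found and tested on the same data.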

How the results depend on the processing

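Median scaling, alone or with an estimated correlation, and leaving out short RNA entries or the 8 h libraries were chosen after seeing the data. Of 2556 recomputed values of 209 named gene results, 2498 were counted as unchanged and 32 were no longer past the threshold. A further 11 newly passed and 15 reversed. A change of sign counted as reversed where the main or the recomputed value passed, and as unchanged where neither did. Except where stated, the cause of a change was not tested. The depth is unknown, so its limits cannot be given.

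With a pseudocount of 0.1, r was 0.425 between 24 h and 96 h of dTAG-13 and 0.668 between dTAG-13 and EPZ-5676 at 96 h. Without a filter more genes were tested, and 15475 were lower at 24 h, 1109 higher and 15088 lower with EPZ-5676, 12 changed between vehicles and 15362 between 24 h and 8 h. A filter of 5 FPKM tested fewer genes: 203 were higher at 8 h, 142 at 24 h, 230 at 96 h and 258 with EPZ-5676, 3 changed between vehicles and 56 in the interaction, and these r were 0.43 and 0.694.

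Scalings that remove the shift between libraries changed most counts by their construction. Median centring of the logs gave 2263 higher and 2290 lower at 8 h, 3261 and 2462 at 24 h, 3410 and 3305 at 96 h, and 4720 and 4232 with EPZ-5676, with 118 between vehicles, 3075 between 24 h and 8 h and 617 in the interaction. Equal totals gave 4051 and 670, 2318 and 1147, 2609 and 2210, and 4972 and 2698 in that order, then 22, 2224 and 272. Median scaling gave 2061 and 2216, 2479 and 2269, 2861 and 3390, and 4150 and 4348, then 95, 2646 and 676, with r of 0.677 between dTAG-13 and EPZ-5676 and 0.569 between 8 h and 24 h. Under median centring, equal totals and median scaling, BCL2 at 96 h of dTAG-13 turned to 0.20, 0.25 and 0.22, RPL5 to 0.03, 0.098 and 0.066, and RPL8 to 0.01, 0.078 and 0.046. These values of RPL5 and RPL8 did not pass (limma adjusted p of 0.122 to 0.9). With EPZ-5676, RPS15 turned to 0.20, 0.38 and 0.25 and RPL8 to 0.16, 0.35 and 0.22. With equal totals MEIS1 with EPZ-5676 (-0.04, adjusted p = 0.445), CDK6 at 24 h (0.121) and 96 h (0.193) and MLLT1 at 24 h (-0.13, 0.128) lost their calls, and ISG15 at 8 h passed (0.0483). MLLT1 at 8 h passed with median centring (0.000474) and median scaling (0.000631).

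With only the groups compared in the fit, 244 genes were higher at 8 h and 16 changed between vehicles. Estimated library weights, which ran from 0.0767 to 569 and did not converge, gave 2773 higher and 5632 lower at 8 h, 382 higher at 24 h, 786 higher at 96 h, 6838 between vehicles, 11891 between dTAG-13 and EPZ-5676 and 1958 in the interaction. Against the 96 h vehicle, 707 were higher and 502 lower at 8 h, and 729 were higher against all 6 vehicle libraries. By total FPKM the shifts were -0.23 at 8 h, -0.56 at 24 h and -0.86 with EPZ-5676. Spearman's rho was 0.81 between 24 h and 96 h, 0.81 between dTAG-13 and EPZ-5676, and 0.706 between 8 h and 24 h. With an estimated correlation 0, 1, 1 and 1 lists were called by camera at 8 h, 24 h, 96 h and with EPZ-5676, and 0, 4, 3 and 2 with median scaling as well. By fry, which does not compare a list with other genes, 4, 25, 24 and 25 were called.

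Without short RNA entries, 30 genes changed between vehicles and 147 in the interaction, and r was 0.843 between 24 h and 96 h, 0.802 between dTAG-13 and EPZ-5676 and 0.73 between 8 h and 24 h. Without the 8 h libraries in the fit, 9 changed between vehicles. Leaving out each library in turn, 224 to 622 genes were higher and 540 to 1881 lower at 8 h, 3 to 6 changed between vehicles and 57 to 89 in the interaction. In these fits r was 0.679 to 0.751 between dTAG-13 and EPZ-5676 and 0.538 to 0.645 between 8 h and 24 h. Groups left with fewer libraries are assumed to vary like the others.

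The column numbers were not taken to pair the libraries: 8 of 45 pairs of same-numbered libraries had r over 0.1 between deviations from their group means (median r -0.018), and 7 of 18 libraries correlated best with their own number. Yet column number 1 had the lowest median in 5 of 6 groups, so a partial pairing is not excluded. With a replicate block, 536 genes were higher and 1853 lower at 8 h, 260 and 9763 at 24 h, 422 and 9543 at 96 h, and 564 and 9778 with EPZ-5676, and 115 differed in the interaction. MLLT1 at 8 h then passed the threshold (adjusted p = 0.0228), and no other named gene changed its call.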

Other observations

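All tests of explanations in this part were chosen after the results were seen. Library medians were lower in all 3 treated groups at 24 h and 96 h. An error of spike-in or loading in single libraries was tested for 9 treated against 6 vehicle libraries. Every treated median lay below every vehicle median, and the exact permutation p was 2e-04, the smallest that 5005 splits can give. These groups were pooled after their medians were seen to be lower, and the 8 h group, which overlapped its vehicle, was left out. This p therefore followed from the choice of groups and does not exclude such an error. A few abundant entries rising in values set to a common total cannot be the cause, because the values had no common total. The gene totals were already known to differ, so this needed no test. The smallest difference in log2 total from vehicle was -0.54 (dTAG-13 at 96 h). Each of the 9 treated libraries had a lower total than any of the 6 vehicle libraries. An error of cell count or spike-in shared by a group stays open, because the vehicle groups differed by -0.12 and a single pair of vehicle groups gives no spread. A lower RNA content per cell may account for the shift, and was not measured otherwise.

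Interferon genes were higher at 8 h of dTAG-13. Unusually low 24 h vehicle libraries are excluded, since 16 of 20 genes were higher against the 96 h vehicle as well. At least 10 of 20 stayed higher whichever library was left out (10 without column number 0 of the 8 h group). The rise of that many genes thus did not rest on a single library. The cut of 10 genes was set after the result and was just met, so it excludes nothing further. Handling of the cells in the hours before the 8 h harvest could have the same effect and stays open, because no vehicle at 8 h is labelled. That 16 of 20 genes were lower at 24 h than at 8 h decides nothing, since 9303 of all 12200 genes were too, and after median scaling 9 were lower and 1 higher.

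Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05. At 8 h the real split gave 1630 genes and the highest other 1. These counts were 9780 and 1 at 24 h, 9688 and 1 at 96 h, 10190 and 1 with EPZ-5676, 5 and 1 between vehicles, 5321 and 4321 between dTAG-13 and EPZ-5676, and 9400 and 2 between 24 h and 8 h. In each of these 1 of the 10 splits gave as many genes. For lists the real and highest other counts were 12 and 14 at 8 h (2 of the 10 splits as many), 14 and 12 at 24 h (1), 14 and 14 at 96 h (2), 15 and 14 with EPZ-5676 (1), 10 and 12 between vehicles (3), 10 and 10 between dTAG-13 and EPZ-5676 (3), and 10 and 11 between 24 h and 8 h (4).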
